A study of Mus musculus with 2 samples.

How the data were processed

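Hepatic gene expression was measured on 1-colour Affymetrix oligonucleotide arrays, hybridised with biotin-labelled cRNA prepared from total liver RNA, per the labels' protocols. The series holds 2 arrays, 1 for each of 2 diets. Per the series' design text, the study used 12 female mice of 2 months of age on a C57BL/6J background, homozygous for a disrupted apolipoprotein E gene, with 6 mice per diet. Whether the RNA on an array was pooled from several mice or came from 1 mouse is not given in the sources used here.

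The deposited values are one intensity per probe set and array on a linear scale, computed by the authors with MAS5, per the submitters' processing notes; the MAS5 version and settings are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The deposited intensities had a 2% trimmed mean of 200.1 on each array, with medians of 44.4 on the array labelled olive oil and 44.6 on the array labelled maslinic acid. They ran from 0.1 to 14375 and from 0.1 to 13030. Detection calls and scanner files were not used here, so signal over background was judged from the signal alone.

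Each of the 2 arrays held 22690 probe sets, of which 64 were control probe sets. The platform annotation named 1 gene for 20393 probe sets and several genes for 691, and 1606 probe sets, controls included, were unnamed here. Of the probe sets naming 1 gene, 20364 matched a gene of the GRCm38.p6 gene table by Entrez number, and 0 symbols changed. The annotation names no genome build, so the gene table served only for names, synonyms and gene order, and no coordinates are given.

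Both arrays were rescaled to a 2% trimmed mean of 500, a factor of 2.50, and signals under 100 were set to 100 after scaling. On the deposited scale this floor is 40.0. A gene was represented by the probe set with the highest mean signal among those naming that gene alone, and counted as measured where that probe set reached 200 after scaling, 80.0 on the deposited scale, on at least 1 array. This left 5911 measured genes of 12393. At the deposited scale, 48.4% of probe sets lay under the floor on the array labelled olive oil and 48.2% on the array labelled maslinic acid. Signals are printed on the deposited scale, and log2 ratios are of the array labelled maslinic acid over the array labelled olive oil. Where the dimmer side lay at the floor, the ratio is a bound and is written as at least N-fold. Low MAS5 signals vary more than high ones, and the floor and the minimum limit what can be said of dim genes.

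With 1 array per diet, no test, standard error or p-value between the diets can be had, and none is given. The number of arrays limits the precision of every value. A gene was described as higher or lower by size alone, with at least 2-fold as the main size and 1.5-fold and 3-fold beside it. Other measured probe sets of the same gene were the only repeat measurement. They are technical and share the hybridisation, and the SD of the log2 ratio between probe sets of 1 gene was 0.23.

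A total of 30 gene lists (pathways, sex-biased liver genes and cell type markers) was fixed before the data were examined. For each list with at least 3 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list below percentile 2.5 or above percentile 97.5 is said to stand apart, as a description of these 2 arrays and not of the diets. Lists overlap in some members, such as Cps1 and Tat in the hepatocyte and urea cycle lists and Cyp2b9, Cyp2b13, Cyp3a16 and Cyp3a44 in the P450 and female-biased lists.

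The rule for named genes was also fixed beforehand. It takes the 12 highest and 12 lowest genes by log2 ratio among those at least 2-fold apart whose further measured probe sets all had the same sign. It adds up to 4 measured members per list with the largest absolute log2 ratio, and the label checks and controls: Apoe, Xist, the Y-linked genes, the hybridisation spikes, Gapdh and Actb. Genes named outside this rule are said to be chosen after their values were seen. Of the Y-linked genes in the rule, Ddx3y is unnamed here.

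The alternatives tried were the deposited scaling, equal medians, quantile normalization and removal of a loess trend of the log2 ratio on mean signal; a floor of 50 or 200; no minimum, a minimum of 400, or a minimum of 200 on the mean of both arrays; the mean of all measured probe sets of a gene; leaving out probe sets ending in _x_at or _s_at, which can read several transcripts; and random lists not matched on signal. The steps were tested on simulated data made from these 2 arrays with a spread of log2 ratios of 0.18. Of 100 measured genes raised 3-fold, 100% were called at least 2-fold higher, and of 100 lowered 3-fold, 99% were called lower, with 0 calls among the other simulated genes, out of 5859 measured. The simulated spread was the same at every signal, while the real log2 ratios had an SD of 0.26 over measured genes and vary more at low signal. The simulation therefore checks the steps and gives no rate of false calls for the real arrays. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.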

Results

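The data are liver expression profiles of mice labelled as apolipoprotein E-deficient. Such mice lack a main ligand for the clearance of lipoprotein remnants and develop high plasma cholesterol. The mice ate chow supplemented with 10% (w/w) olive oil, or with 10% (w/w) olive oil enriched in maslinic acid, a pentacyclic triterpene of olives, for 4 weeks. The comparison asks which hepatic genes differ in expression when the oil contains maslinic acid. It rests on 1 array per diet, so no difference has a replicate check. A total of 5911 genes reached the minimum signal on at least 1 of the 2 arrays.

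The targeted gene was examined first. Apoe, read by 1 probe set, had a signal of 407.7 on the array labelled olive oil and 7630 on the array labelled maslinic acid, 18.7-fold higher, a log2 ratio of 4.23 and the highest among genes above the floor on both arrays. Both diet groups are labelled as homozygous knockouts, yet Apoe lay above the floor on both arrays. Without detection calls or probe positions, the 407.7 on the array labelled olive oil cannot show whether intact Apoe RNA was present. The level on the array labelled maslinic acid goes against the label, unless the probes lie outside the disrupted part of the gene or the probe set is at fault. Neither is known here. Probe position alone would not give the 18.7-fold difference, since both arrays are labelled with the same knockout. With the label in doubt, every direction in the text is between the arrays as labelled. Genes beside Apoe in the gene table, chosen after their values were seen, differed little: Apoc1 had a log2 ratio of -0.15, Apoc2 of 0.17, Apoc4 of 0.11 and Tomm40 of 0.02.

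Sex-linked genes went with the female label on both arrays. Xist, the RNA that silences the second X chromosome of female cells, had signals of 2867 and 2136 on the arrays labelled olive oil and maslinic acid with 1 probe set, and of 2252 and 2486 with another. The remaining, dimmer Xist probe set read 169.9 and 88.7. The 6 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty had signals of at most 9.2 on either array, under the floor.

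**Figure D1:**
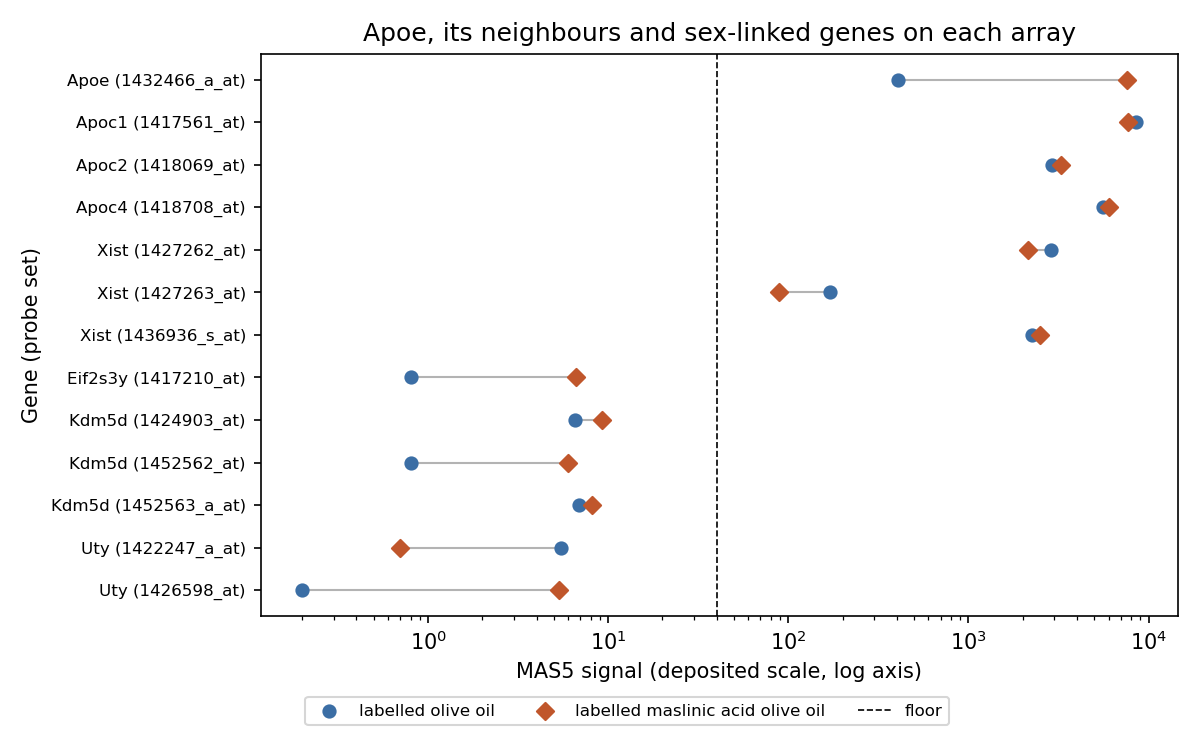
MAS5 signals (deposited scale, log axis) of Apoe, 3 neighbouring apolipoprotein genes, Xist and Y-linked genes, with 1 row per probe set, a circle for the array labelled olive oil, a diamond for the array labelled maslinic acid and a dashed line at the floor. Apoe lies at 407.7 and 7630, its neighbours nearly coincide, and the Y-linked probe sets stay at or under 9.2.

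The arrays were otherwise alike. Over the measured genes the log2 signals correlated with r = 0.987 across genes, which are not independent replicates, and 97.0% of genes lay within 1.5-fold. The 9 hybridisation spike probe sets, added in equal amount, had a mean log2 ratio of 0.07 with an SD of 0.075. The 3' to 5' signal ratio of Gapdh was 0.915 on the array labelled olive oil and 0.895 on the array labelled maslinic acid, and that of Actb was 2.31 and 2.77. Actb itself had a log2 ratio of -0.22. The 5' control probe set of 18S ribosomal RNA read 3553 on the array labelled olive oil and 197.7 on the other, while its 3' probe set read 413.9 and 294.0. The 50 brightest genes had a median log2 ratio of -0.14, and 47 of them were lower on the array labelled maslinic acid.

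The 12 genes highest on the array labelled maslinic acid held Apoe and 4 cytochrome P450 genes. Cyp2b9 had a signal of 18.7 on the array labelled olive oil and 660.4 on the array labelled maslinic acid, at least 16.5-fold higher. Cyp2b13, at 1.9 and 252.2, was at least 6.30-fold higher, and Cyp2b10, the phenobarbital-inducible member of the same subfamily, was at least 2.93-fold higher at 21.4 and 117.1. Cyp3a16 was 2.77-fold higher. Dbp, a transcription factor driven by the circadian clock, read 61.7 and 214.0, 3.47-fold higher, and its other measured probe set was at least 2.5-fold higher. The immunoglobulin genes Ighm and Igkv8-30 were 2.90-fold and 3.10-fold higher, although the 3 probe sets of Ighm ranged in log2 ratio from 0.49 to 1.54. Tcl1b3, a member of the Tcl1 family, read 76.1 and 711.4, 9.35-fold higher, on a probe set of the kind that can read several transcripts. Lims1, an adaptor of integrin signalling, was 2.62-fold higher, the protamine gene Prm1 2.41-fold and Fkbp8 2.35-fold.

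Among genes above the floor on both arrays, the lowest on the array labelled maslinic acid was Marco, a scavenger receptor of macrophages, with signals of 338.1 and 84.6, a log2 ratio of -2.0. Hmox1, which encodes the inducible haem oxygenase, followed at 129.9 and 37.2, at least 3.25-fold lower. The clathrin adaptor gene Ap2b1 had a log2 ratio of -1.39 and Ctnnd1, which encodes p120 catenin, of -1.35. The stress-responsive Gadd45g and the TGF-beta inhibitor Smad7 had log2 ratios of -1.22 and -1.19, Wdfy3 of -1.19 and Rbmx of -1.13. Lce1h and the sestrin gene Sesn2 were each at least 2.17-fold lower. Dynll2, a dynein light chain gene, read 990.2 and 447.1, a log2 ratio of -1.15, but its other probe set gave -0.17. Srek1 gave -1.22 and, with its other probe set, -0.36.

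In all, 18 genes were at least 2-fold higher and 18 at least 2-fold lower on the array labelled maslinic acid, out of 5911. At 1.5-fold the counts were 87 and 93, and at 3-fold 6 and 2. The genes at least 2-fold apart were dim, with a median mean signal of 118.7 against 253.9 over all measured genes. With a minimum signal of 400 in place of 200 the counts were 12 higher and 7 lower. Of the named genes, Cyp2b10, Hmox1, Gadd45g, Smad7, Wdfy3, Rbmx, Lce1h and Sesn2 were not measured under that minimum and lay less than 2-fold apart with a floor of 200. Among all genes at least 2-fold apart, further measured probe sets existed for 5 and went the same way in all 5. At 1.5-fold they did so in 29 of 40 genes, and over all measured genes in 872 of 1814.

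**Figure D2:**
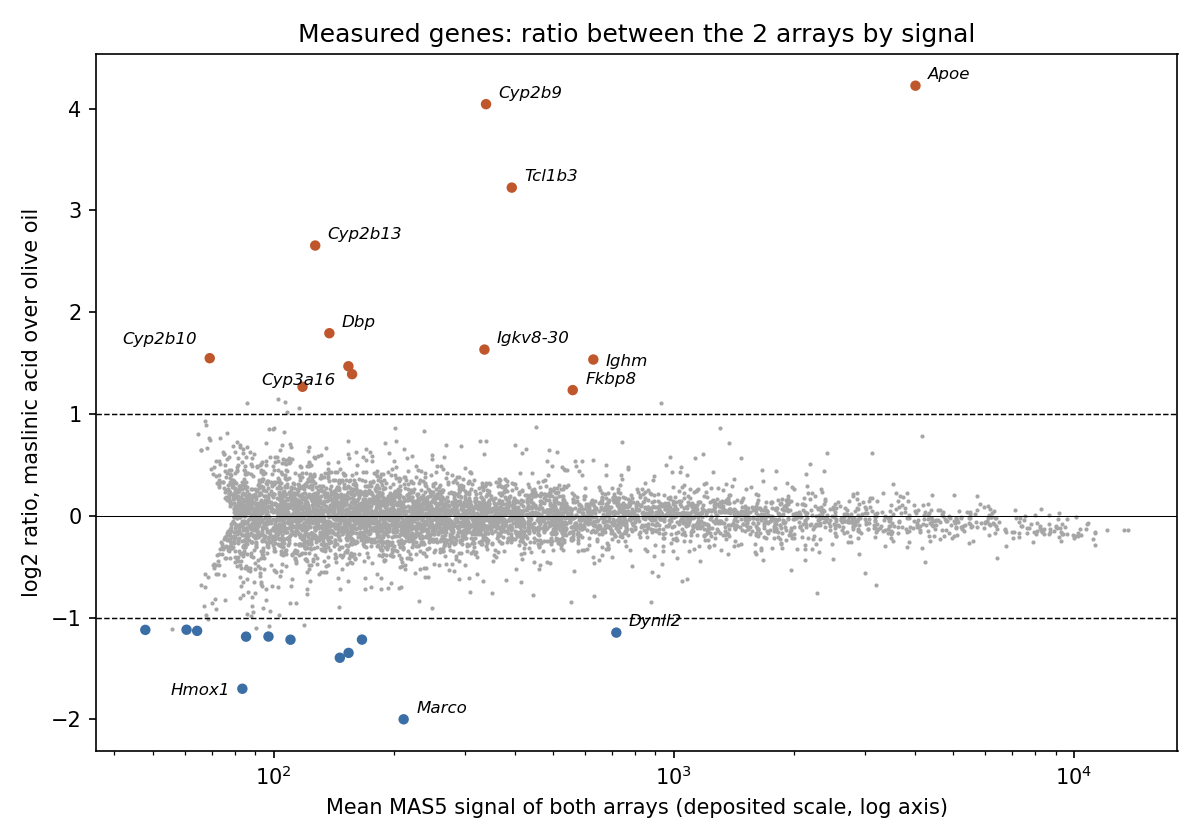
Log2 ratio of the array labelled maslinic acid over the array labelled olive oil against the mean MAS5 signal of both arrays (deposited scale, log axis), with 1 point per measured gene and dashed lines at 2-fold. Coloured points are the 12 highest and 12 lowest named genes. Apoe lies at 4.23, and genes with 1 side at the floor are drawn at their bound, such as Cyp2b9 at 4.04.

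Of the 30 gene lists, 26 had at least 3 measured members, and 8 of these stood apart from matched random lists. For lists of unrelated genes 1.3 would do so. Members of a list can vary together and some lists share members, so the excess does not measure chance between the 2 arrays. The female-biased liver genes stood apart the furthest on the array labelled maslinic acid, with a median log2 ratio of 0.64 (percentile 100) over 8 measured members. Of these, 7 were higher, led by Cyp2b9, Cyp2b13 and Cyp3a16, with Cyp17a1, a steroid hydroxylase, 1.66-fold higher. The 4 measured male-biased genes had a median of -0.07 (percentile 32.7), with Gstp1 at -0.15 and Cyp2d9 at 0.14. The wider list of P450 families 1 to 3 had a median of -0.0015 over 22 members (percentile 92.3): 4 members were at least 2-fold higher, and the others lay between -0.45 (Cyp1a2) and 0.36 (Cyp3a13), both chosen after their values were seen. With quantile or loess scaling this list also stood apart.

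Among lipid pathways, genes of cholesterol synthesis and uptake were slightly higher on the array labelled maslinic acid, with a median log2 ratio of 0.11 (percentile 99.7). Of the 19 measured members 11 were higher, among them Mvk (0.53), the squalene epoxidase gene Sqle (0.31) and Msmo1 (0.29), and 8 were lower, among them Sc5d (-0.31). None reached 1.5-fold. Fatty acid and triglyceride synthesis had a median of -0.11 (percentile 0.665). In that list 10 of 19 members were lower, including the desaturase gene Fads2 (-0.48, and -0.13 on its other probe set), the acetyl-CoA carboxylase gene Acacb (-0.36) and the regulator Srebf1 (-0.35), and 9 were higher, including Scd2 (0.34). This list lay within the central range with quantile scaling (percentile 21.3) and with the mean of all probe sets (percentile 4.84), and hepatocyte markers were also lower on the same array.

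Other lipid lists did not stand apart. Fatty acid oxidation and PPAR alpha targets had a median of -0.03 (percentile 49.9) over 29 members, with Fgf21, a hormone of the fasting liver, at -0.86 (-0.18 with a floor of 200), Ehhadh at -0.44, Acaa1a at 0.62 (0.11 on its other probe set) and Acot3 at 0.40. Bile acid synthesis and transport had a median of -0.0035 (percentile 72.7) over 21 members, with Akr1d1 at 0.48 (0.04 on its other probe set) and Abcc2 at -0.30. Lipoprotein metabolism had a median of -0.10 (percentile 5.45), with 13 of 21 members lower, including Apob (-0.29). In that list Pltp, the phospholipid transfer protein gene, was 1.54-fold higher, Apoa4 1.53-fold, with a log2 ratio of 0.998 on its other probe set, and Vldlr 1.32-fold. In glucose and glycogen metabolism, with a median of 0.01 (percentile 86.5) over 14 members, Igfbp1 had a log2 ratio of -0.68 and Ppargc1a of -0.28, although the 4 probe sets of Ppargc1a ranged from -0.28 to 0.30.

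Immune and inflammatory lists lay higher or within the range. The 5 measured lymphocyte and antigen presentation markers were all higher on the array labelled maslinic acid, with a median of 0.33 (percentile 99.9): Ighm at 1.54, and the MHC class II genes H2-Aa at 0.50, H2-Eb1 at 0.33 and H2-Ab1 at 0.32. With no minimum signal that median was 0. The acute phase list had a median of 0.015 (percentile 98.1), with 14 of 28 members higher and 14 lower; the metallothionein gene Mt2 was 2.16-fold higher, Lcn2 1.58-fold and Mt1 1.36-fold, while Orm2 lay at -0.31. Its sign turned with a minimum of 400 and without probe sets ending in _x_at or _s_at. The interferon list, with a median of 0.08 (percentile 94.0) over 15 members, held Psmb9 at 0.45 and Igtp at 0.40. Among 6 cytokine and NF-kappaB target genes (median 0.14, percentile 90.1) Cxcl1 lay at 0.73, Il1b at -0.65 and Nfkbia at -0.37.

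Cell type markers differed by type. Hepatocyte markers were lower on the array labelled maslinic acid, with 10 of 11 below 0 and a median of -0.18 (percentile 0.115); Ttr, the transthyretin gene, lay at -0.23, Alb at -0.21 and Hpd at -0.18. Hnf4a lay at -0.22, but its 3 probe sets ranged from -0.22 to 0.64. The named markers Ttr, Alb and Hpd are bright, and the 50 brightest genes also had a median of -0.14. With quantile scaling the hepatocyte median was -0.059 (percentile 5.32). With the loess trend on signal removed it was -0.091 (percentile 0.415), so part of the shift followed signal strength. Stellate cell and matrix markers were higher, with 8 of 12 above 0 and a median of 0.20 (percentile 99.9): Acta2, the smooth muscle actin gene, at 0.35, Lum at 0.34 and Vim at 0.27, against Col4a1 at -0.26. Macrophage and Kupffer cell markers had a median of 0.07 (percentile 95.1), with Marco at -2.0 and C1qb at 0.43 as the extremes of 15 members, although the 3 probe sets of C1qb ranged from 0.10 to 0.43, and Adgre1 at -0.26. Endothelial markers had a median of -0.08 (percentile 14.8), with Kdr at -0.49 and Cdh5 at -0.32. Few markers of other tissues were measured: Alas2 of the erythroid list at 0.68, Cela1 of the exocrine pancreas list at -0.54, Fabp4 of the adipocyte list at 0.43, and 0 cholangiocyte markers.

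**Figure D3:**
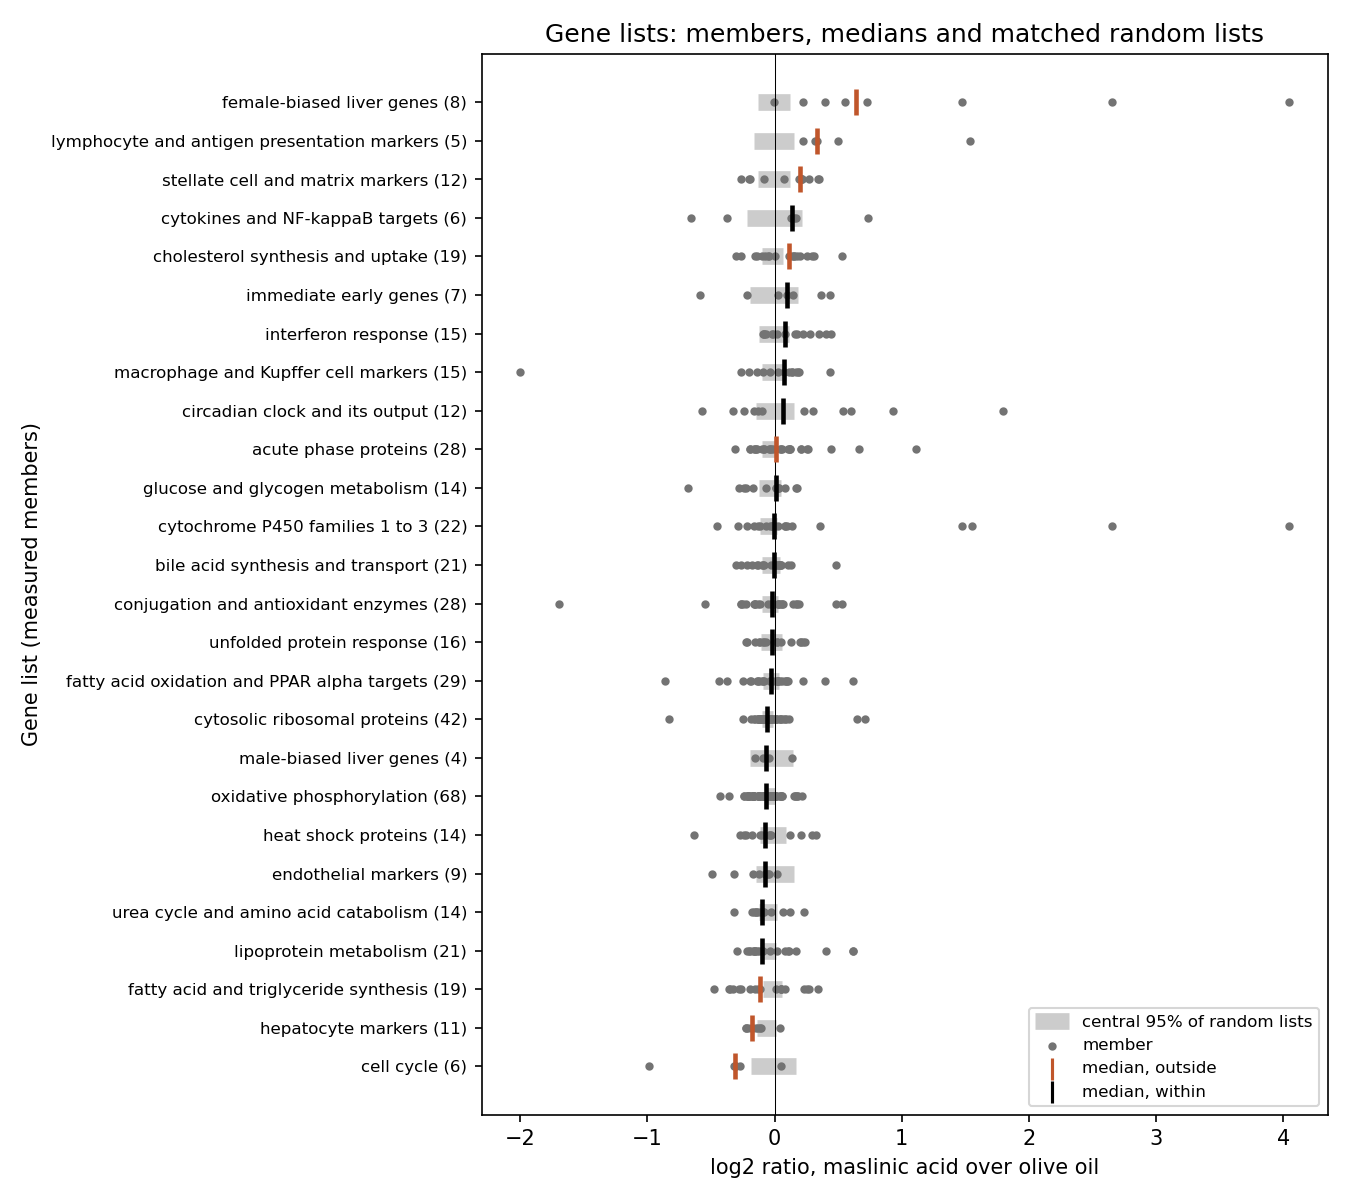
Log2 ratios of the array labelled maslinic acid over the array labelled olive oil for the 26 gene lists with at least 3 measured members. Points are members, vertical marks are list medians and grey bars hold the central 95% of matched random lists; the 8 coloured marks, from -0.31 (cell cycle) to 0.64 (female-biased genes), lie outside their bars.

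The cell cycle list was lower on the array labelled maslinic acid, with 5 of 6 measured members below 0 and a median of -0.31 (percentile 0.14). The growth arrest gene Gadd45b lay at -0.99, the cyclin gene Ccnd1 at -0.32 and Rrm2 at -0.30. Mcm7 lay at -0.31, but its 3 probe sets ranged from -0.31 to 0.08. Gadd45b is a stress gene, so the lowest member is not a gene of division. The remaining measured members, named after their values were seen, were Cdkn1a at -0.27 and Pcna at 0.05. Only 6 of the 21 members on the array were measured. The list lay within the range without probe sets ending in _x_at or _s_at (percentile 3.25) and with no minimum signal. Antioxidant and conjugation genes had a median of -0.02 (percentile 72.4) over 28 members; beside Hmox1, the glutathione transferase genes Gsta2 and Gstm2 lay at -0.55 and 0.48 and the quinone reductase gene Nqo1 at 0.53.

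The remaining lists lay within the range of random lists. Clock genes had a median of 0.07 (percentile 78.4) over 12 members, with Dbp at 1.79, Cry2 at 0.93 and Nr1d1 at 0.60, against Per1 at -0.57. With the minimum on the mean of both arrays, 8 members were measured and the clock median turned to -0.11 (percentile 6.3). Cry2, Nr1d1 and Per1 are dim, and with a floor of 200 they lay at 0.14, 0.18 and -0.10. Heat shock genes had a median of -0.07 (percentile 13.9), with Hspa1b at -0.63 on the probe set used and at -0.51 or lower on all 3 of its probe sets, Hsp90aa1 at 0.32 with 3 probe sets ranging from -0.36 to 0.32, and Hsph1 at 0.29. The unfolded protein response had a median of -0.02 (percentile 53.4), with Manf at 0.24 and Sdf2l1 at -0.23. Immediate early genes had a median of 0.10 (percentile 86.7) over 7 members, with Dusp1 at -0.59 and Egr1 at 0.44. The urea cycle and amino acid catabolism list had a median of -0.10 (percentile 9.84), with Got1 at -0.32 and Prodh at 0.23. Oxidative phosphorylation had a median of -0.07 (percentile 5.78) with 51 of 68 members lower, including Atp5md at -0.43. Cytosolic ribosomal protein genes had a median of -0.06 (percentile 47.7) over 42 members, with the dim Rps27 at -0.83 and Rpl39 at 0.71.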

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

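Each result here comes from probe sets outside the gene comparison, which read differently on the 2 arrays. The 5' control probe set of 18S ribosomal RNA had a signal of 3553.1 on the array labelled olive oil and 197.7 on the array labelled maslinic acid, 18-fold apart, while the middle probe set (320.9 and 261.2) and the 3' probe set (413.9 and 294.0) differed by 1.23-fold and 1.41-fold.

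Of 799 measured probe sets that name no gene or several genes, 3 were at least 2-fold higher on the array labelled maslinic acid and 2 were lower. The higher ones each name several genes and are left unnamed. Their signals on the arrays labelled olive oil and maslinic acid were 405.2 and 1184.6, 475.0 and 1106.3, and 38.8 and 102.3, where 38.8 lies under the floor. No explanation of these values was tested.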

How the results depend on the processing

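All alternatives were chosen before the data were examined. With 1 array per diet no array can be left out, so nothing could be recomputed without the array with the higher Apoe signal. No paired analysis was possible because each diet has 1 array. Of 1292 values of named genes under the alternatives, 1275 moved by less than 1.5 times and 0 reversed a difference of at least 2-fold. Many named genes are less than 1.5-fold apart, so these counts do not show that their direction held. The sign turned for Hnf4a (up to 0.64), Ppargc1a (up to 0.09), Hsp90aa1 (down to -0.07) and Atp5j2 (up to 0.02). The 24 extreme genes stayed at least 2-fold apart the same way in 235 of 264 values, were less far apart in 12 and were not measured in 17. Without _x_at and _s_at probe sets, Tcl1b3, Igkv8-30, Lims1, Prm1 and Lce1h were not measured. Of 312 list values 298 kept their side of the central range. The cholesterol, female-biased and stellate lists stood apart in all 12 alternatives run on them. Some alternatives could change little. The deposited arrays already had nearly equal trimmed means, so the deposited scaling nearly repeated the main setting. A floor of 50 left the medians of these lists unchanged. The counts of values that held include such settings.

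Counts of genes at least 2-fold lower went from 18 to 7 with a floor of 200 and to 7 with a minimum of 400 (higher: 12 in both, so the share of higher genes went from 50% to 63.2%); 1.5-fold gave 87 and 93 and 3-fold gave 6 and 2. The share of genes within 1.5-fold, 97.0%, was 98.0% with a floor of 200, with no minimum and with a minimum of 400, and 97.4% with the minimum on the mean. Genes whose probe sets all went the same way made up 100% and, with no minimum, 40%, since that setting admits probe sets under the floor.

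Quantile scaling gave medians of -0.035 for fatty acid synthesis, 0.054 for P450 genes and -0.059 for hepatocyte markers, and loess 0.067 for P450 genes. With no minimum the cell cycle and lymphocyte medians were 0 and 0, since most members lie at the floor on both arrays. The acute phase median turned to -0.013 with a minimum of 400 and to -0.021 without _x_at and _s_at probe sets; the latter gave -0.20 for cell cycle. The mean of all probe sets gave -0.072 for fatty acid synthesis, and the minimum on the mean 0.12 for interferon genes. Against unmatched random lists the acute phase median (0.015) no longer stood apart and the lipoprotein (-0.10) and oxidative phosphorylation (-0.067) medians did. The lipoprotein median was -0.0045 (percentile 60.6) with quantile scaling and -0.011 (percentile 77.4) with the mean of all probe sets. Except as stated, the cause was not tested. Signal over background limits the dim genes: bounds such as that of Cyp2b9 move with the floor (log2 ratio 5.04 with a floor of 50, 3.04 with 200).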

Other observations

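In this part, the immunoglobulin and MHC class II groups, the genes of this paragraph other than Ighm and Igkv8-30, and the tests of causes for Apoe, Cyp2b and Dbp were chosen after the results were seen. The scaling alternatives, the Y-linked check and the male-biased list were fixed before, and only their use as such tests was chosen after. The measured immunoglobulin genes, with Jchain counted among them, were all higher on the array labelled maslinic acid, 4 of 4, with a median log2 ratio of 1.33. Beside Ighm and Igkv8-30, Jchain, which joins immunoglobulin polymers, was 2.18-fold higher (67.3 and 146.4) and Igha 1.82-fold. The 4 measured genes of the MHC class II group, H2-Aa, H2-Ab1, H2-Eb1 and the invariant chain gene Cd74, were higher by a median of 0.33. In steroid and bile acid conjugation, the abundant sulfotransferase gene Sult2a2 was 1.72-fold higher (3060 and 5268). The other genes at least 2-fold higher were Eci3 (2.22-fold), Tox (2.16-fold), Clcn5 (2.08-fold) and Ctla2a (2.03-fold), and those at least 2-fold lower were Apbb3 (at least 2.16-fold), and Rbfox2, Zeb2, Stard8, Erf and Topors, with log2 ratios from -1.10 to -1.0.

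Apoe was 18.7-fold higher on the array labelled maslinic acid although all mice are labelled as lacking it. A cause in the scaling is excluded, since the lowest log2 ratio of Apoe under the 4 scaling alternatives was 4.22. Signal of another apolipoprotein transcript is also excluded as the whole cause: the highest log2 ratio among all measured probe sets of the other 12 measured apolipoprotein genes was 0.998, on a probe set of Apoa4. RNA of mice with an intact Apoe gene on that array may account for it, but the 40 nearest measured neighbours of Apoe, which could carry sequence of another strain, had absolute log2 ratios at percentile 79.6 of random lists, and the length of such a stretch is not known, so this stays open. An effect of the diet on transcripts of the disrupted gene, and a fault of the 1 Apoe probe set, stay open and untested.

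Cyp2b9, Cyp2b13 and Cyp2b10 were higher on the same array. Male liver on the array labelled olive oil, where female-biased genes would be low, is excluded, since the highest Y-linked signal on either array was 9.2. A shift of sex-biased genes as a group may be involved: the 6 measured female-biased genes other than Cyp2b had a median log2 ratio of 0.47 (percentile 100), but the male-biased list, at percentile 32.7, lay within the central range, and its 4 measured members are too few to decide. Signal shared between the Cyp2b paralogs, an effect of the diet and a difference in Apoe status between the arrays stay open and untested.

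Dbp was 3.47-fold higher on the array labelled maslinic acid. Livers taken at different times of day may give such a difference. The 5 genes taken to peak near Dbp, without Dbp itself, lay 0.25 above 3 opposed clock genes in mean log2 ratio. This was at percentile 91.0 of random draws, and Per1 and Hlf went the other way (-0.57 and -0.24). Cry1 (0.54) and Bhlhe40 (-0.17), named after their values were seen, and Cry2 (0.93) were in neither group. The contrast depends on that choice, so the genes do not decide. Noise of dim probe sets stays open too. The 2 Dbp probe sets had log2 ratios of 1.79 and at least 1.32, where the latter is a bound set by the floor, and the log2 ratios of probe sets no brighter than these had an SD of 0.34. An effect of the diet was not tested.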
